A study of Mus musculus with 6 samples.

How the data were processed

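RNA-seq counts were analysed for 6 libraries of skin from female BALB/c mice aged 6 to 8 weeks. Per the labels' protocols, total RNA was isolated from frozen skin, and 300 ng per sample went into stranded total RNA libraries depleted of ribosomal RNA, sequenced as single-end reads of 50 bp. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2 2.1.0, featureCounts 1.6.1 and DESeq2 1.20.0 were used with the mm10 genome. The authors deposited raw counts per gene, per the series description from featureCounts, with exon coordinates and NCBI gene numbers. The strand setting and the treatment of reads with several matches are not given in the sources used here, so genes with close copies (keratins, keratin-associated proteins, Sprr, Stfa and histone genes) and overlapping or antisense genes are uncertain.

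Groups were taken from the sample labels. Control, bleomycin and bleomycin with EHP-101 had 1 library each and bleomycin with ajulemic acid had 3. A deposited table merged with samples of another series held the same counts for the 6 libraries, with 0 differing values, and its 6 other sample columns were not used. The table listed 27179 genes. Symbols were found for 25293 gene numbers and 1886 had none. Mitochondrial ribosomal RNA took 26.5% of the counts in control, 19.8% in bleomycin, 17.9% in EHP-101 and 17.3, 26.1 and 18.5% in the ajulemic acid libraries. The pairs of ajulemic acid libraries differed far beyond sampling noise, with a chi-square per degree of freedom of at least 35.9, so none was counted as a duplicate.

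The main test was edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with filterByExpr (minimum count 10, 17377 genes tested), TMM normalization and robust quasi-likelihood F-tests (two-sided) in 1 fit of all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 2 residual degrees of freedom came only from the ajulemic acid group; the common biological coefficient of variation was 0.267. There were 6 comparisons. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry (limma 3.58.1). The test with an estimated correlation rested on the 2 residual degrees of freedom and had little power. A list that it did not call is therefore not shown to be unchanged. The text gives list medians and, for some lists, their percentile among 10000 random lists of the same size matched on mean expression in 20 bins; both camera's p and this percentile are computed across genes, and the percentile ignores correlation between them. CPM were computed with TMM-scaled library sizes, intervals of single libraries are exact 95% Poisson intervals for counting error only, and list values per library used log2 CPM with a prior count of 3.

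The design, 40 gene lists, a panel of 25 genes, the alternatives and the rule for named genes were chosen before the data were examined. Where no gene passed in a comparison, the rule named the 5 genes of smallest unadjusted p in each direction with a mean log2 CPM of at least 2; for each list called by camera it named the 3 members of smallest p in the list's direction; and it named the panel. For the treated libraries against control it named the panel only. Some genes that the rule names are not reported here. A further 7 lists (hepatocyte, lung, kidney, pancreas, heart, developing and regenerating muscle, and small noncoding RNA) were drawn up after the data were seen; kidney and pancreas had 3 and 2 tested genes and were not analysed further.

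The scripts were tested on simulated counts for 17377 genes with 200 changed. For bleomycin against control edgeR recovered 40 of 100 genes changed 4-fold and 95 of 100 changed 16-fold, with 17 unchanged genes called, and DESeq2 65 and 96 with 36. For EHP-101 against bleomycin edgeR recovered 43 and 96 with 13, and for ajulemic acid against bleomycin 77 and 96 with 24. To allow for libraries shared between comparisons, 20 sets of counts with no effect were simulated from the tagwise dispersions. In these edgeR called between 5.55 and 7.60 genes per comparison on average. Each of these means exceeded edgeR's calls on the real counts. The dispersions, from 2 residual degrees of freedom, were taken as exact, so the simulated counts are a rough guide and not a calibrated null. The alternatives were DESeq2 1.42.0, limma-trend, other scalings and filters, no robust option, a minimum fold of 1.5, library sizes without tissue and RNA lists, and leaving out each ajulemic acid library.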

Results

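Total RNA of skin from female BALB/c mice was sequenced in 4 conditions. Control skin was represented by 1 library, and so was skin exposed to bleomycin, a DNA-damaging agent used in mice to model the dermal fibrosis of scleroderma. Bleomycin-exposed skin treated with EHP-101, an oral formulation of the cannabidiol aminoquinone VCE-004.8, was represented by 1 library, and bleomycin-exposed skin treated with ajulemic acid, a synthetic cannabinoid, by 3. The libraries held 15728362 counts in control, 15542255 in bleomycin, 15483701 in EHP-101 and 14291592, 18639641 and 19837682 in the 3 ajulemic acid libraries. Doses and times were not given in the labels. Differences between single libraries have no replicate check, and values of the ajulemic acid group are given as mean ± SD of n = 3. In the tests the single libraries were assumed to vary like the ajulemic acid libraries, and the labels do not say whether these came from separate animals, so p-values measure only the spread between these samples, which may be technical. Expression is in CPM, counts scaled to library size, and gene list medians are of log2 fold changes.

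The first comparison asked how skin exposed to bleomycin differed from control skin. The bleomycin library had higher medians over lists of matrix proteases, inflammation and keratinocyte activation and a lower one over adipocyte markers. Lox, the lysyl oxidase that cross-links collagen (gene 16948, chromosome 18, 52517238 to 52529708 in mm10), was at 20.8 CPM in control (95% Poisson interval 18.5 to 23.2, for counting error only) and 95.9 in bleomycin, a log2 fold change of 2.21 (SE 0.21). The network collagen Col8a1 (gene 12837, chromosome 16, 57624256 to 57754737) was at 9.86 and 114 CPM. The adipocyte fatty acid binding protein Fabp4 was at 848 CPM in control and 214 in bleomycin. None of these differences passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment.

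The major fibrillar collagens were close between these libraries. Col1a1 was at 1664 CPM in control and 1684 in bleomycin, a log2 fold change of 0.02 (SE 0.29), and Col3a1 at 2478 and 3091 CPM, a log2 fold change of 0.32 (SE 0.32). Of the 35 genes of the collagen and matrix list, 26 had a positive log2 fold change and the median was 0.30, at percentile 99.97 of 10000 random lists matched on expression. In this comparison 31 of 40 lists lay outside the central 95% of their random lists, which ignore correlation between genes, and none was called with an estimated correlation. Of the members, 6 passed when adjusted over the list alone and 0 over all genes. Among the 15 matrix proteases and inhibitors the median was 0.97 with 13 positive, and 4 passed when adjusted over the list alone. Timp1, an inhibitor of metalloproteinases, was at 2.83 and 16.7 CPM, the macrophage elastase Mmp12 at 9.33 and 35.3 CPM, and the collagenase Mmp13 at 0.723 and 10.8 CPM. Acta2, the smooth muscle actin of myofibroblasts, was at 80.6 and 85.8 CPM, and Tgfb1 at 11.2 and 14.3 CPM.

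Of 26 inflammatory cytokine and chemokine genes, 22 had a positive log2 fold change in bleomycin, with a median of 0.90. The monocyte chemokine Ccl2 was at 3.22 CPM in control and 13.9 in bleomycin, and the adhesion molecule Vcam1 at 6.18 and 24.2 CPM. The median was 0.65 over 30 interferon response genes, 0.42 over 25 macrophage markers and 1.62 over 11 neutrophil markers. Of 20 genes of the p53 and DNA damage list, 19 were higher in bleomycin (median 0.52), among them the p53 target Eda2r at 6.18 and 26.6 CPM. The keratinocyte activation list had a median of 0.82 over 15 genes. Its summed CPM, where abundant genes weigh most, did not rise, at 1234 in control and 1114 in bleomycin. Krt16, a keratin of activated epidermis (gene 16666, chromosome 11, 100246091 to 100248902), was at 21.3 and 99.3 CPM. The cornified envelope protein Rptn, of the differentiated keratinocyte list, was at 33.1 and 249 CPM.

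All 25 white adipocyte markers were lower in the bleomycin library (median -0.96), and 6 passed when adjusted over the list alone. The adipokine Adipoq was at 265 CPM in control and 86.6 in bleomycin, and Pparg, the nuclear receptor that directs adipogenesis, at 46.5 and 19.3 CPM. Targets of PPAR had a median of -0.81, with 23 of 26 negative. All 37 hair shaft and anagen follicle genes were also lower (median -3.97), as were all 26 proliferation genes (median -1.11) and 12 of 13 melanocyte markers (median -1.64). In centred log2 CPM the melanocyte list was at 0.46 in control and -1.175 in bleomycin. In the ajulemic acid libraries it was at 0.52, -1.68 and 1.43, so it also varied widely within 1 group. Medians were positive for 28 skeletal muscle markers (1.48) and 15 Schwann cell and nerve markers (1.24). The other genes of smallest p that the naming rule gave, none of which passed, were Snord17, C1qtnf3 and Xirp1 among the higher and Tkt, Retnla, Gpc3 and Dpp4 among the lower; the type 2 macrophage product Retnla was at 77.3 CPM in control and 4.11 in bleomycin.

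**Figure D1:**
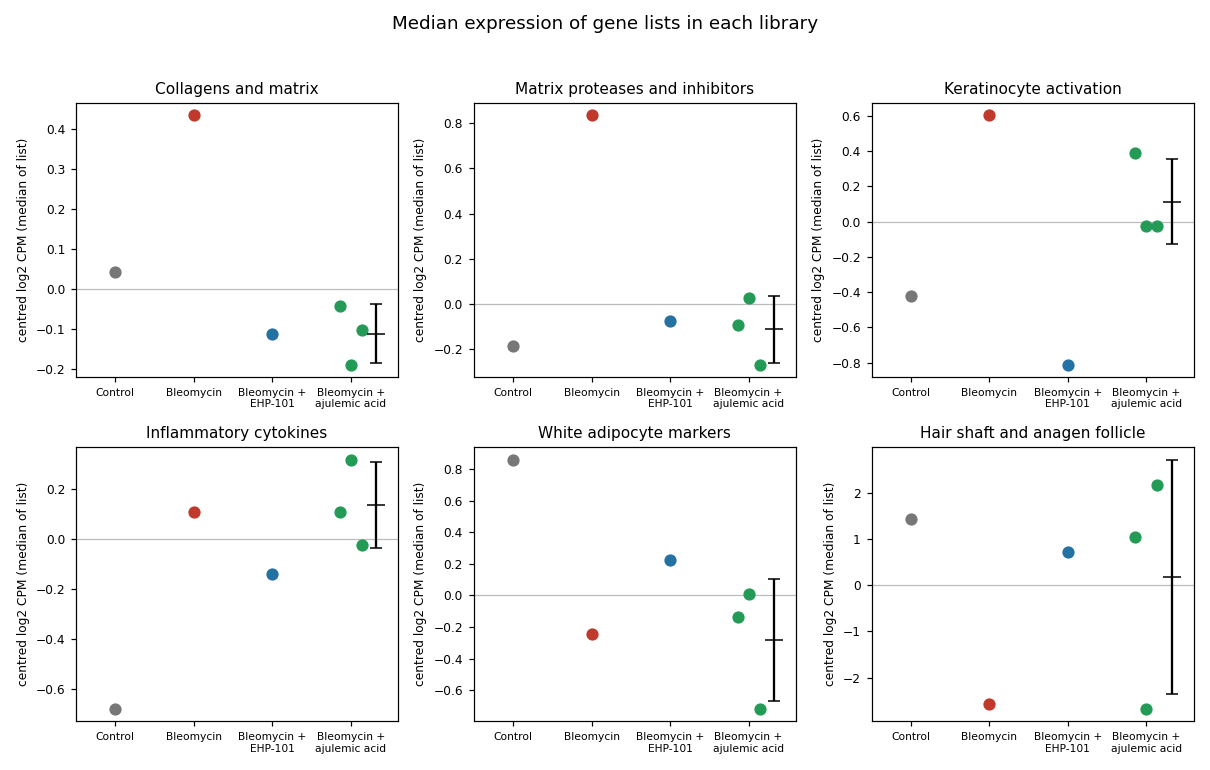
Each point is 1 library, and its height is the median over a gene list of log2 CPM centred on the mean of the 6 libraries; the bar beside the ajulemic acid points is their mean ± SD (n = 3), and the scale differs between panels. The collagen and matrix list was at 0.43 in bleomycin and between -0.19 and -0.04 in the ajulemic acid libraries, and the hair list was at -2.56 in bleomycin and -2.67 in ajulemic acid replicate 2.

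By edgeR's quasi-likelihood test 0 of 17377 genes were higher and 0 lower in bleomycin than in control (smallest adjusted p = 0.354); 817 were higher and 365 lower at an unadjusted p under 0.05. DESeq2 called 128 higher and 37 lower, where 20 simulated sets with no effect gave it 33.3 ± 6.91 (SD) calls in both directions together, and limma called 0. Without ajulemic acid replicate 3, edgeR called 141 higher and 38 lower, and without replicate 2 it called 6 and 2. DESeq2 called 30 higher and 4 lower without replicate 1, and 168 higher and 264 lower without replicate 2. By camera with its preset correlation 17 of 40 lists were called higher and 10 lower. All of these calls were lost with an estimated correlation (adjusted p = 0.463 to 0.629). With 2 residual degrees of freedom that test had little power, here and in the other comparisons. The loss therefore cannot decide whether the lists differed.

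The second comparison asked how the skin treated with EHP-101 differed from bleomycin alone. Medians over the matrix, protease and keratinocyte activation lists were negative in the EHP-101 library and the median over adipocyte markers was positive, and none of these lists was called with an estimated correlation. Krt16 was at 99.3 CPM in bleomycin and 17.9 in EHP-101, Rptn at 249 and 15.9 CPM, and the cornified envelope precursor Sprr1b at 17.4 and 2.69 CPM. Lox was at 95.9 and 34.8 CPM and the stromelysin Mmp11 at 23.2 and 3.97 CPM. None of these differences passed edgeR's test.

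Of the 35 collagen and matrix genes, 30 had a negative log2 fold change in EHP-101 against bleomycin, with a median of -0.64, below all 10000 matched random lists. In this comparison 26 of 40 lists lay outside the central 95% of their random lists, and none was called with an estimated correlation. Of these genes 1 passed when adjusted over the list alone, and 0 over all genes. Col1a1 was at 1684 CPM in bleomycin and 903 in EHP-101, a log2 fold change of -0.90 (SE 0.29), and Col3a1 at 3091 and 1517 CPM, a log2 fold change of -1.03 (SE 0.32). Periostin, Postn, was at 782 and 398 CPM. The collagen triple helix repeat protein Cthrc1 was at 12.4 and 2.20 CPM. The median of the 15 proteases and inhibitors was -0.80 and 14 were lower, with Mmp12 at 35.3 and 9.34 CPM. The 15 keratinocyte activation genes had a median of -1.59 with 11 lower, and 23 of 25 differentiated keratinocyte markers were lower (median -0.71). The summed CPM of the keratinocyte activation list was not lower, at 1114 in bleomycin and 1284 in EHP-101.

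Immune lists also had negative medians in the EHP-101 library, -0.43 over 26 cytokine and chemokine genes, -0.39 over 25 macrophage markers and -0.84 over 24 T and NK cell markers. These lists also varied within the ajulemic acid group. In centred log2 CPM the cytokine list was at 0.11 in bleomycin, -0.14 in EHP-101 and 0.11, 0.32 and -0.02 with ajulemic acid. The macrophage list was at 0.13, -0.22 and 0.16, 0.39 and -0.12 in the same order, and the T and NK list at 0.37, -0.33 and -0.01, 0.55 and -0.31. Ccl2 was at 13.9 CPM in bleomycin and 9.46 in EHP-101, and Vcam1 at 24.2 and 14.03 CPM. Interferon response genes had a median of 0.08. Of 25 white adipocyte markers, 21 were higher (median 0.47). Their list was at -0.24 in bleomycin and 0.23 in EHP-101 in centred log2 CPM, and at -0.14, 0.01 and -0.72 in the ajulemic acid libraries. Fabp4 was at 214 CPM in bleomycin and 449 in EHP-101, the adipokine leptin, Lep, at 21.1 and 62.9 CPM, and Adipoq at 86.6 and 173 CPM. The other genes of smallest p among the higher were Nnat, Trarg1, Fosb and Pappa2. All 37 hair follicle genes (median 3.40) and all 26 proliferation genes (median 1.05) were higher in the same library. In centred log2 CPM the proliferation list was at -0.76 in bleomycin, 0.29 in EHP-101 and 0.03, -0.50 and 0.62 in the ajulemic acid libraries. Replicate 2 was the lowest ajulemic acid library in this list and in the hair list.

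edgeR's quasi-likelihood test called 0 genes higher and 0 lower in EHP-101 than in bleomycin, with 100 higher and 229 lower at an unadjusted p under 0.05. DESeq2 called 2 higher and 8 lower, and limma called 0. The 20 simulated sets with no effect gave DESeq2 31.2 ± 6.97 (SD) calls, more than the real counts did, so those sets are a rough guide only. Without ajulemic acid replicate 2, DESeq2 called 134 higher and 21 lower, and without replicate 1 it called 0 and 3. camera called 8 lists higher and 17 lower. None was called with an estimated correlation (adjusted p = 0.346 to 0.862).

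**Figure D2:**
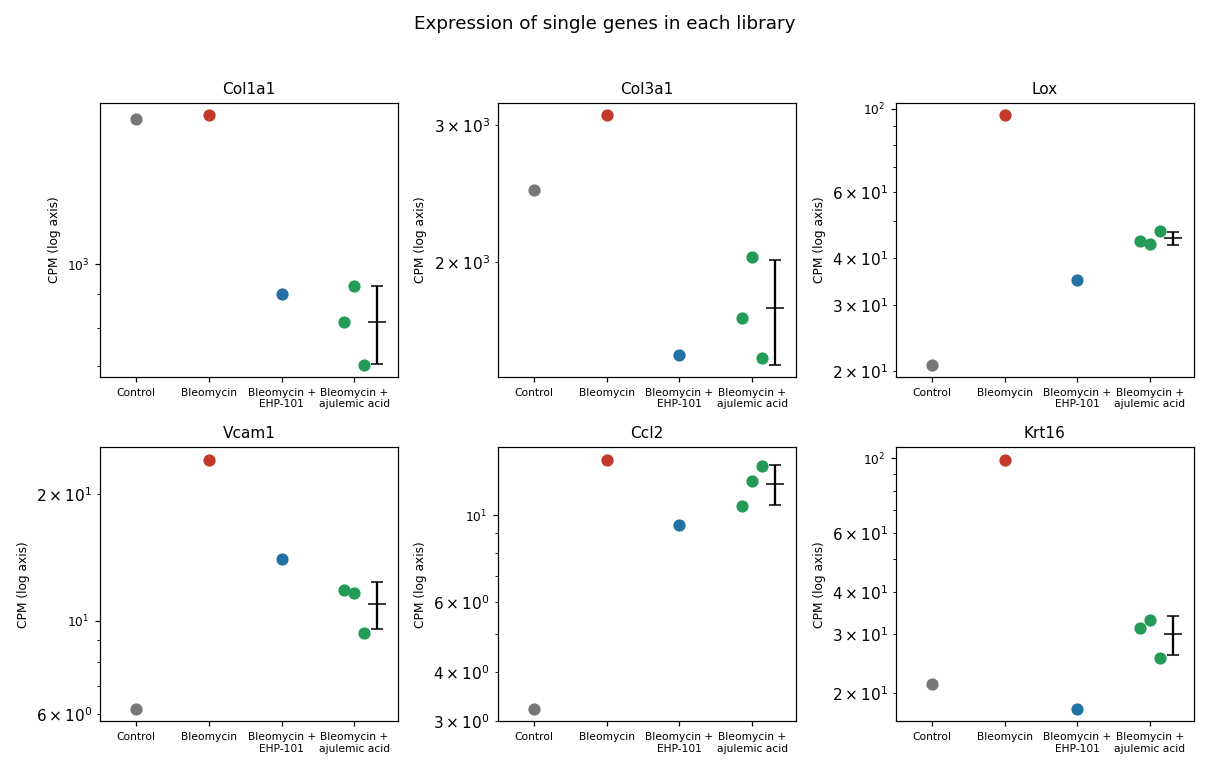
Each point is the expression of a gene in 1 library in CPM on a log axis, and the bar beside the ajulemic acid points is their mean ± SD (n = 3). Col1a1 was at 1684 CPM in bleomycin and between 704 and 927 in the ajulemic acid libraries, and Krt16 at 99.3 CPM in bleomycin and between 25.4 and 33.0 in the ajulemic acid libraries.

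The third comparison asked how the skin treated with ajulemic acid differed from bleomycin alone. Medians over the collagen, protease, keratinocyte activation and Schwann cell lists were negative with ajulemic acid, and none of these lists was called with an estimated correlation. Col1a1 was at 1684 CPM in bleomycin and 816 ± 111 (SD, n = 3) with ajulemic acid, a log2 fold change of -1.04 (SE 0.23), and Col3a1 at 3091 and 1740 ± 268 CPM, a log2 fold change of -0.83 (SE 0.25). Lox was at 95.9 and 45.1 ± 1.92 CPM, and Col8a1 at 114 and 46.9 ± 6.46 CPM. Krt16 was at 99.3 and 29.9 ± 3.96 CPM, and Rptn at 249 and 35.2 ± 9.72 CPM. None of these differences passed edgeR's test.

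Of the 35 collagen and matrix genes, 31 were lower with ajulemic acid (median -0.55), 15 passed when adjusted over the list alone and 0 over all genes. The fibrillar collagen Col5a1 was at 303 CPM in bleomycin and 159 ± 8.85 with ajulemic acid. The 15 proteases and inhibitors had a median of -1.23 with 13 lower, and 4 passed when adjusted over the list alone. Mmp12 was at 35.3 and 7.83 ± 1.47 CPM and the metalloproteinase Adam12 at 35.9 and 11.2 ± 2.46 CPM. Of 15 Schwann cell and nerve markers, 14 were lower (median -1.06) and 8 passed when adjusted over the list alone. All 28 skeletal muscle markers had a negative log2 fold change as well (median -0.56), but in centred log2 CPM their median was 0.56 in bleomycin and -0.10, 0.41 and -0.45 in the ajulemic acid libraries, so that replicate 2 lay close to bleomycin. The keratinocyte activation list had a median of -0.73 with 10 of 15 lower, and of -0.48 without replicate 3. In centred log2 CPM it was at 0.60 in bleomycin and 0.39, -0.02 and -0.03 in the ajulemic acid libraries. Its summed CPM was 1114 in bleomycin and 1634, 874.7 and 2298 in the ajulemic acid libraries, so only replicate 2 was lower by that measure.

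Inflammatory genes were divided with ajulemic acid, 14 of 26 being higher and 12 lower (median 0.02, and -0.16 without replicate 2). Ccl2 was at 13.9 CPM in bleomycin and 12.03 ± 1.38 with ajulemic acid, and Vcam1 at 24.2 and 10.96 ± 1.38 CPM. Macrophage markers had a median of -0.02. White adipocyte markers had a median of 0.01 and targets of PPAR one of -0.06, and Pparg was at 19.3 and 19.2 ± 6.14 CPM. In centred log2 CPM the adipocyte list was at -0.24 in bleomycin and -0.14, 0.01 and -0.72 in the ajulemic acid libraries, and the PPAR list at -0.15 against -0.08, 0.00 and -0.58, so replicate 3 lay below bleomycin and the others above it. The 5 genes of smallest p among the higher were the clock gene Per2, at 8.28 and 23.3 ± 3.26 CPM, and Pappa2, Gsdma3, Dpp4 and Fosb. All 37 hair follicle genes had a positive log2 fold change (median 3.70), but replicate 2 of the ajulemic acid group, at -2.67 in centred log2 CPM, was close to bleomycin at -2.56.

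Genes of smallest p among the lower included products of hepatocytes. The inter-alpha-trypsin inhibitor chain Itih4 was at 11.3 CPM in bleomycin and 0.487 ± 0.077 with ajulemic acid. Apolipoprotein H (Apoh), the bile salt exporter Abcb11 and plasminogen (Plg) had log2 fold changes of -5.37, -4.47 and -5.09. In a list of 38 hepatocyte transcripts drawn up after these values were seen, all 38 were lower with ajulemic acid (median -5.78). Albumin, Alb, also chosen after its values were seen, had 10318 counts in control, 7437 in bleomycin and 7449 in EHP-101, and 82, 220 and 35 in the 3 ajulemic acid libraries.

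**Figure D3:**
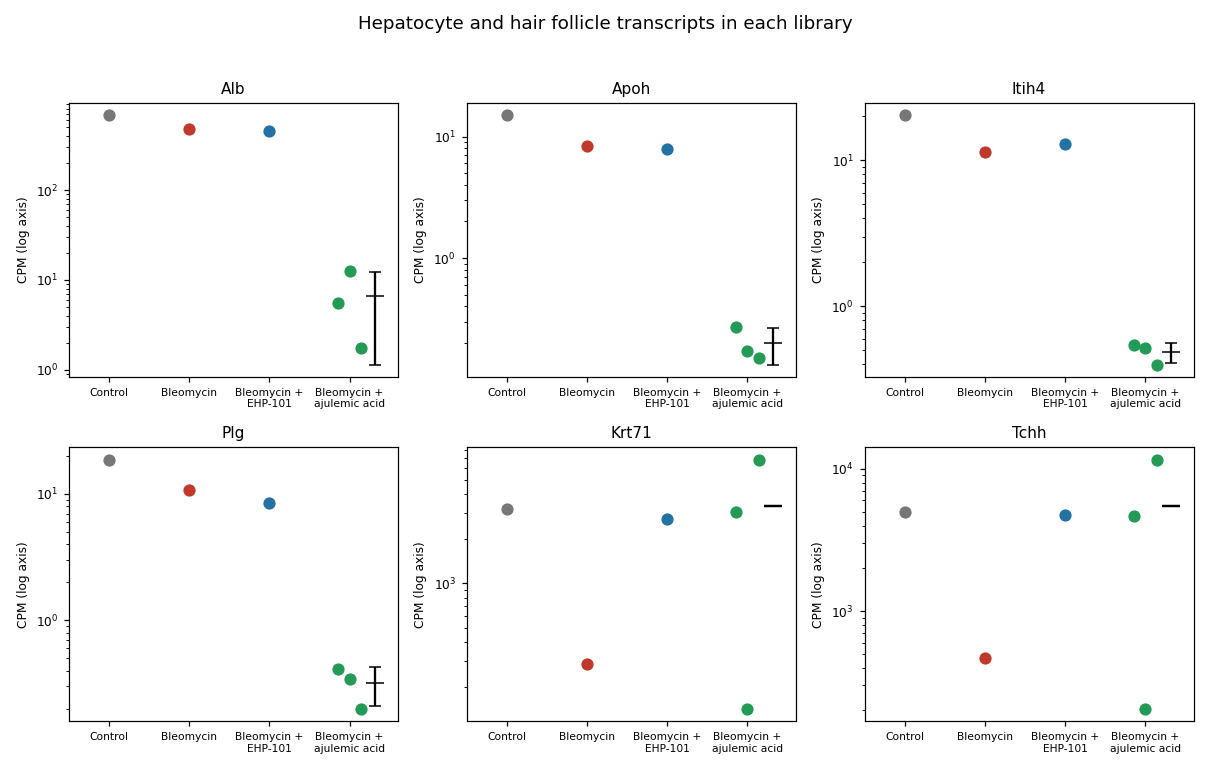
Each point is the expression of a gene in 1 library in CPM on a log axis, and the bar beside the ajulemic acid points is their mean ± SD (n = 3), or the mean alone for Krt71 and Tchh, hair follicle genes chosen after their values were seen, whose SD exceeded the mean. Albumin was at 678, 477 and 455 CPM in control, bleomycin and EHP-101 and between 1.75 and 12.6 with ajulemic acid, while the hair keratin Krt71 was at 286 CPM in bleomycin and between 142 and 6880 with ajulemic acid.

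edgeR's quasi-likelihood test called 0 genes higher and 0 lower with ajulemic acid than in bleomycin (smallest adjusted p = 0.109), with 108 higher and 558 lower at an unadjusted p under 0.05, while DESeq2 called 4 higher and 99 lower against 32.9 ± 8.24 (SD) in both directions in the simulated sets and limma called 0. Without ajulemic acid replicate 3 edgeR called 2 higher and 91 lower, without replicate 2 it called 7 and 63, and with no filter on low counts it called 41 lower. DESeq2 called 0 higher and 47 lower without replicate 1, 296 higher and 129 lower without replicate 2, and 1 higher and 57 lower without replicate 3. camera called 5 lists higher and 10 lower. None was called with an estimated correlation (adjusted p = 0.507 to 0.903).

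The treated libraries were also set against control. Col1a1 was at 1664 CPM in control, 903 in EHP-101 and 816 ± 111 with ajulemic acid. The collagen and matrix list had a median of -0.08 in EHP-101 and -0.18 with ajulemic acid against control. Ccl2, at 3.22 CPM in control, was at 9.46 in EHP-101 and 12.03 ± 1.38 with ajulemic acid. Adipoq was at 265 CPM in control, 173 in EHP-101 and 111 ± 31.4 with ajulemic acid. Against control, 27 of 30 interferon response genes were higher in EHP-101 (median 0.71) and 29 of 30 with ajulemic acid (median 0.95), and white adipocyte markers had medians of -0.67 and -1.15.

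By edgeR's test 0 genes were called in EHP-101 against control, with 508 higher and 298 lower at an unadjusted p under 0.05, DESeq2 called 94 higher and 28 lower against 30.4 ± 4.07 (SD) in both directions in the simulated sets, and limma called 0. Without ajulemic acid replicate 3 edgeR called 72 higher and 19 lower there, and without replicate 2 it called 7 and 2, while DESeq2 called 29 and 5 without replicate 1. With ajulemic acid against control edgeR called 0 higher and 6 lower, with 524 higher and 713 lower at an unadjusted p under 0.05, DESeq2 called 98 and 178, and limma called 0. The simulated sets with no effect gave 7.50 ± 5.08 (SD) calls by edgeR and 32.5 ± 5.09 by DESeq2 in this comparison, so edgeR's 6 were no more than they gave. Those sets are a rough guide and do not tell which single calls are false. Among edgeR's calls, and named here after their values were seen, were the hepatocyte genes Itih4, Apoh, Itih2, Abcb11 and Plg, with log2 fold changes of -5.37, -6.22, -4.71, -5.26 and -5.88 (edgeR's adjusted p = 0.0484 for Plg and 0.0466 for the others), lower than control in 3 of 3 libraries. With hepatocyte and lung transcripts left out of the test 0 genes were lower, and without ajulemic acid replicate 1 also 0, against 165 without replicate 2 and 231 without replicate 3. Higher genes numbered 46 without replicate 2 and 137 without replicate 3, and DESeq2 called 30 higher and 79 lower without replicate 1. Of 40 lists, camera called 21 in EHP-101 and 23 with ajulemic acid against control. None was called with an estimated correlation (smallest adjusted p = 0.529 and 0.497).

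A further question was whether genes that differed between bleomycin and control went back in treated skin. By edgeR no gene was called in both comparisons. By DESeq2, 8 genes were called in opposite directions in bleomycin against control and EHP-101 against bleomycin, and 14 for ajulemic acid. The bleomycin library entered both sides, and 20 simulated sets with no effect gave 8.65 ± 2.62 (SD) and 11.8 ± 3.41 such genes; independent lists would share 0.0653 higher then lower and 0.00472 lower then higher for EHP-101, and 0.808 and 0.00943 for ajulemic acid. Without ajulemic acid replicate 3 edgeR gave 8 such genes for ajulemic acid. Of the 128 genes DESeq2 called higher in bleomycin, 85 were lower in EHP-101 than in bleomycin and 111 with ajulemic acid. Among the 128 higher genes of smallest p in each simulated set, called or not, 107.1 ± 4.40 (SD) and 112.55 ± 2.33 were. Of the 37 called lower, 28 were higher in EHP-101 than in bleomycin and 29 with ajulemic acid, against 33.9 ± 1.25 and 36.2 ± 0.77 of the 37 lower genes of smallest p. None of these 4 counts was above the simulated mean. The simulated sets had no bleomycin effect, so their top genes came from noise and fell back for that reason. Genes with a real bleomycin effect need not fall back as often, so these counts cannot tell whether genes went back. Over all genes, the log2 fold changes of bleomycin against control and of EHP-101 against bleomycin had a Pearson r of -0.62, against -0.50 in the simulated sets, with a covariance of -0.426 against -0.244, a difference of -0.182. For ajulemic acid r was -0.53 against -0.62, with a covariance of -0.423 against -0.244, a difference of -0.179. For ajulemic acid the excess was thus in the covariance only, and r was weaker than in the simulated sets. The log2 fold changes of EHP-101 and of ajulemic acid, each against bleomycin, had a covariance of 0.417 against 0.244, a difference of 0.173. Those comparisons share only the bleomycin library. With 1 bleomycin library no split of the shared samples was possible, so part of the excess in covariance may come from that library. Genes are also not independent replicates. Hair follicle genes were left in. In centred log2 CPM their list was at 1.43 in control, -2.56 in bleomycin, 0.73 in EHP-101 and 1.05, -2.67 and 2.17 in the ajulemic acid libraries. Their share of the excess was not tested, so the excess cannot be read as genes going back.

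The last comparison set the treatments side by side, with doses and times not given. The estimates for Col1a1 and Col3a1 differed little between the treatments, with wide intervals. Col1a1 had a log2 fold change of 0.15 in EHP-101 against ajulemic acid (95% interval -0.47 to 0.76) and Col3a1 one of -0.20 (-0.88 to 0.48), and the 35 collagen and matrix genes had a median near 0, with 17 positive and 18 negative. Lep was at 62.9 CPM in EHP-101 and 24.3 ± 3.94 with ajulemic acid, a log2 fold change of 1.37 (0.80 to 1.94), and Sprr1b at 2.69 and 9.01 ± 1.17 CPM, a log2 fold change of -1.74 (-2.53 to -0.96). Neither passed edgeR's test over all genes.

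Of 25 white adipocyte markers 21 were higher in EHP-101 than with ajulemic acid (median 0.48), and 1 passed when adjusted over the list alone. The medians of 28 skeletal muscle markers (0.51), 19 endothelial markers (0.42) and 26 targets of PPAR (0.25) were also positive. In centred log2 CPM the muscle list was at 0.47 in EHP-101 and -0.10, 0.41 and -0.45 in the ajulemic acid libraries, the endothelial list at 0.33 against -0.05, 0.02 and -0.45, and the PPAR list at 0.15 against -0.08, 0.00 and -0.58. Medians were negative for 15 keratinocyte activation genes (-0.74), 25 differentiated keratinocyte markers (-0.53), 20 sebaceous gland markers (-0.52) and 25 macrophage markers (-0.31). The differentiated keratinocyte list was at -0.36 in EHP-101 against 0.32, 0.30 and -0.46 in the ajulemic acid libraries and the sebaceous list at -0.49 against -0.02, 0.58 and -0.52, so replicate 3 did not lie above EHP-101 in either. The cannabinoid receptor gene Cnr1 was at 6.71 CPM in EHP-101 and 3.68 ± 0.382 with ajulemic acid, and Cnr2 at 3.05 and 4.92 ± 1.66 CPM. The genes of smallest p among the higher included the hepatocyte transcripts Itih4, Apoh, Plg and Itih2, and among the lower were Sprr1b, Cst6, Gba2, Zdbf2 and Rgp1. edgeR called 0 genes (343 higher and 69 lower at an unadjusted p under 0.05), DESeq2 called 63 higher and 1 lower against 30.45 ± 8.38 (SD) in both directions in the simulated sets, and limma called 0. Without ajulemic acid replicate 3 edgeR called 65 higher and 2 lower, without replicate 2 it called 18 higher, and with no filter on low counts 16. DESeq2 called 32 higher and 0 lower without replicate 1, 60 higher and 12 lower without replicate 2, and 36 higher and 10 lower without replicate 3. camera called 5 lists higher and 9 lower, and none with an estimated correlation (adjusted p = 0.931 to 0.996).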

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

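All tests of explanations in this part were chosen after the results were seen. Among 40 gene lists and 24 tested panel genes, those in which the EHP-101 library lay on one side of the bleomycin library and all 3 ajulemic acid libraries on the other were picked out. The median difference in log2 CPM from bleomycin over the endothelial markers was 0.11 in EHP-101 and -0.29, -0.03 and -0.64 in the ajulemic acid libraries. For the NRF2 and oxidative stress list it was -0.06 in EHP-101 and 0.06, 0.01 and 0.18 with ajulemic acid. Pecam1 differed from bleomycin by 0.10 in EHP-101 and by -0.27, -0.27 and -0.71 with ajulemic acid, and Cnr1 by 0.39 in EHP-101 and by -0.32, -0.61 and -0.42. The opposite directions from bleomycin were seen, not tested. The difference between EHP-101 and ajulemic acid was tested in the fit of all 6 libraries and did not pass by edgeR for Pecam1 (log2 fold change 0.50, adjusted p = 1) or Cnr1 (0.87, adjusted p = 1). camera called the endothelial list higher in EHP-101 at its preset correlation (median 0.42, adjusted p = 8.55e-07) but not with an estimated one (adjusted p = 0.931), and did not call the NRF2 list (median -0.14, adjusted p = 0.154). No group was large enough for a search for single outlying samples.

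Hepatocyte transcripts made up 0.150% of the counts in control, 0.101% in bleomycin and 0.0941% in EHP-101, and 0.0028, 0.00343 and 0.00217% in the ajulemic acid libraries. Depth or scaling is argued against, since the median log2 fold change of all tested genes between ajulemic acid and bleomycin was 0.019 where the list's was -5.777. A candidate explanation is liver RNA or reads from 1 source in the control, bleomycin and EHP-101 libraries; the log2 counts of the 38 genes had a smallest Pearson r of 0.853 between pairs of those libraries (highest 0.977), across genes that are not independent replicates, below the bound of 0.9 set for a single source, so it stays open. An effect of ajulemic acid stays open too: all 3 ajulemic acid libraries lay below bleomycin, but the design cannot separate the drug from anything else that set that group apart. None of the 38 genes was in another list.

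Hair follicle genes were lower in bleomycin than in control by 3.99 in centred log2 CPM. Differences in hair follicle stage between samples, whatever their group, may account for this, since the list varied by 4.85 within the 3 ajulemic acid libraries, more than the difference itself; the labels do not say whether these came from separate animals. Bleomycin exposure cannot be excluded: of the 4 drug-treated, bleomycin-exposed libraries 1 was at or above control, and every such library was also drug-treated.

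The matrix list had a negative median against bleomycin in both treated groups (-0.64 in EHP-101 and -0.55 with ajulemic acid), though not every member was lower. The list was not called with an estimated correlation, and no single gene passed edgeR's test. Hair follicle stage is argued against as the cause, because the matrix list varied by only 0.15 within the ajulemic acid libraries, whose hair list varied by 4.85, where bleomycin exceeded their mean by 0.54. Fewer fibroblasts in treated samples could not be excluded: the fibroblast list lay 0.58 above the matrix list with ajulemic acid, within the SD of its 20 members outside the matrix list (0.73). The fibroblast median against bleomycin was 0.03 with ajulemic acid and -0.13 in EHP-101, where the SD was 0.85. These SDs are the spread of single genes and not the error of a median, so the bound was wide and the test weak. A bleomycin library that was high for a reason other than bleomycin cannot be told apart from an effect of the drugs, since the matrix list was at -0.18 with ajulemic acid against control and only 1 bleomycin library was sequenced. In summed CPM, where abundant genes weigh most, the list was at 11120 in control and 13860 in bleomycin. It was lower than control in EHP-101 (7960) and in the ajulemic acid libraries (8412, 8744 and 7878). Control too had 1 library, so this does not decide the question.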

How the results depend on the processing

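Leaving out the hepatocyte and lung lists, DESeq2 without single libraries, and list medians under other scalings and without single libraries were tests chosen after the results were seen. The 6 comparisons under all alternatives gave 181 counts of genes, lists and opposite calls within 1.5 times the reported one and 57 beyond it. Of the counts of genes called by DESeq2 without single libraries, 15 stayed within 1.5 times and 21 moved beyond it. List medians stayed within the spread in 425 cases and moved beyond it in 13, described below. Of the values for named genes, 1790 kept their direction and side of the threshold, 130 passed it newly (60 of them under DESeq2), 21 lost it and 10 turned direction. No paired analysis was possible because the groups share only the replicate number 3.

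In bleomycin against control DESeq2 called 128 genes higher and 37 lower, where edgeR called 0 and 0. In EHP-101 against bleomycin it called 2 and 8, in ajulemic acid against bleomycin 4 and 99, in EHP-101 against control 94 and 28, in ajulemic acid against control 98 and 178, and in EHP-101 against ajulemic acid 63 and 1. The opposite calls were 8 for EHP-101 and 14 for ajulemic acid by DESeq2. With no filter on low counts, 41 genes were lower in ajulemic acid against bleomycin, 27 higher and 126 lower in ajulemic acid against control, and 16 higher in EHP-101 against ajulemic acid. With no scaling factors 1 gene was higher and 34 were lower in ajulemic acid against control. The 6 genes lower there became 0 with a CPM of at least 1 in all libraries, with limma, against a fold of 1.5, and with hepatocyte and lung lists left out; the filter and the left-out lists removed such genes from the test by construction, and otherwise the cause was not tested.

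Leaving out each ajulemic acid library in turn gave 0 to 141 genes higher and 0 to 38 lower in bleomycin against control. It gave 0 to 7 higher and 0 to 91 lower in ajulemic acid against bleomycin, and 0 to 72 higher and 0 to 19 lower in EHP-101 against control. In ajulemic acid against control it gave 0 to 137 higher and 0 to 231 lower, and in EHP-101 against ajulemic acid 0 to 65 higher and 0 to 2 lower. The opposite calls for ajulemic acid ranged from 0 to 8. In bleomycin against control and EHP-101 against control the compared libraries stayed the same. In the first, the median log2 fold change of all genes was -0.0058 with all libraries and -0.0089 without replicate 2. The calls there changed through the spread taken from the ajulemic acid libraries. Otherwise the cause was not tested, and each such fit had 1 residual degree of freedom fewer. The calls of gene lists in all 6 comparisons became 0 with an estimated correlation and 0 by fry. The test with an estimated correlation had little power in this design, so its 0 calls do not decide the question.

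Of the 13 list medians that moved, 10 were of ajulemic acid against bleomycin. The matrix list went from -0.55 to -0.65 without replicate 3, and the protease list from -1.23 to -1.05, -0.93 and -1.05 without replicates 1, 2 and 3. The keratinocyte activation list went from -0.73 to -0.48 and the hepatocyte list from -5.78 to -5.26 without replicate 3. Without replicate 2 the inflammatory list went from 0.02 to -0.16, the neutrophil list from -0.73 to -1.13, the Schwann cell list from -1.06 to -1.29 and the hepatocyte list to -6.55. With no scaling factors the matrix list went from -0.64 to -0.56 in EHP-101 against bleomycin and from near 0 to 0.10 in EHP-101 against ajulemic acid, where the hepatocyte list went from 5.30 to 4.84 without replicate 3. The cause was not tested.

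No gene that turned direction had passed the test, and the cause was not tested. With no scaling factors Tgfb1 had a log2 fold change of 0.04391 in EHP-101 against bleomycin and 0.00526 in EHP-101 against ajulemic acid, where it ranged from -0.1767 without replicate 3 to 0.009497 without replicate 2. In ajulemic acid against bleomycin Tgfb1 ranged from -0.04359 without replicate 2 to 0.1426 without replicate 3. In that comparison Pparg was at 0.006841 with no filter, -0.3051 without replicate 2, 0.05938 without replicate 1 and 0.1791 without replicate 3. Adgre1 was at -0.007026 with upper-quartile factors, -0.003502 by limma, -0.1684 without replicate 2 and 0.2146 without replicate 3. With no scaling factors the median of all genes in EHP-101 against control shifted by 0.13. Depth limited genes of few counts, such as Apoh with 3 or 4 counts in each ajulemic acid library.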

Other observations

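The tests in this part used gene lists and genes chosen after the data were seen. All 20 genes of developing and regenerating muscle were higher in bleomycin than in control (median log2 fold change 3.76); edgeR called 0 of 17377 genes in this comparison. The embryonic myosin Myh3 was at 1.71 CPM in control, 104 in bleomycin, 156 in EHP-101 and 49.7 ± 20.8 (SD, n = 3) with ajulemic acid. The myogenic regulator Myog was at 0.591, 11.9, 18.6 and 9.12 ± 3.17 CPM in the same order, and the imprinted transcript H19 at 29.6, 259, 257 and 164 ± 32.7 CPM. The list was also higher than control in EHP-101 (median 4.35, 20 of 20 genes) and with ajulemic acid (median 3.16, 20 of 20 genes), so all 5 libraries from bleomycin-exposed skin lay above the single control library. The same held for the 28 markers of mature skeletal muscle, at -0.93 in control, 0.56 in bleomycin, 0.47 in EHP-101 and -0.10, 0.41 and -0.45 in the ajulemic acid libraries in centred log2 CPM.

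Of 15 small noncoding RNA genes, 14 were higher in bleomycin than in control (median 2.09), 14 in EHP-101 (median 2.29) and 15 with ajulemic acid (median 2.58). In centred log2 CPM the list was at -1.985 in control, 0.18 in bleomycin, 0.40 in EHP-101 and 0.48, 0.32 and 0.40 with ajulemic acid. The pattern thus rests on the 1 control library, and a property of that library cannot be told apart from bleomycin exposure. Rmrp, the RNA of RNase MRP, was at 498 CPM in control, 2067 in bleomycin, 1935 in EHP-101 and 2198 ± 134 with ajulemic acid. Sftpc, the surfactant protein C of lung epithelium, had 266 counts in control, 51 in bleomycin, 3 in EHP-101 and 7, 1 and 4 in the ajulemic acid libraries; the 12 lung transcripts had a median of -1.74 in bleomycin against control. The 9 heart transcripts had a median of 0.38 in the same comparison. In a principal component analysis of log2 CPM the component with 44.5% of the variance set bleomycin and ajulemic acid replicate 2 apart from the other libraries. Bleomycin and replicate 2 also had the lowest hair list medians, -2.56 and -2.67 in centred log2 CPM.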
